A study of Mus musculus with 2 samples.

How the data were processed

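H3K27ac, acetylation of lysine 27 on histone H3, is a chromatin mark of active promoters and enhancers. It was measured by ChIP-seq in limb tissue of mouse embryos at embryonic day 10.5, per the labels. There was 1 group with 2 biological replicates, pooled from 69 embryos (replicate 1) and 51 embryos (replicate 2) of both sexes. The labels name separate pools of embryos for the replicates, and no second stage, tissue or treatment, so no comparison between groups was made.

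The deposited data were 4 peak lists on the mouse genome build mm10: 1 per replicate, 1 called on both replicates together (the pooled list) and 1 named replicated peaks. Per the file notes deposited with the samples, each replicate's list came from that library's alignments and a control alignment, the pooled list from both libraries and both controls, and the replicated list from the pooled list and both replicate lists. The aligner, the peak caller, its version and its settings, and the rule that selects the replicated peaks, are not given in the sources used here. The fold of a peak is a linear ratio of the ChIP library over its control, as deposited by the authors. The −log10 p and −log10 q of each peak are the authors' own values too, and the lowest −log10 p in every list lay just over 2. The deposited score column is a display value scaled within each list and entered no result. Fold and −log10 p were used only to describe, rank or filter peaks within a list, except where the replicates' folds at shared peaks are set side by side, which is said there. Read counts and library sizes were not analysed here because peak lists hold none: the depth is unknown, and no interval or floor that needs it is given.

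Peaks were placed on GRCm38, the assembly of mm10, with protein-coding genes of GENCODE M21. The annotation held 21911 genes and 93444 transcription start sites (TSSs) after 27 repeated symbols were left out. No peak ran past a chromosome end and no list held overlapping peaks. Peaks on unplaced contigs (9 in the replicated list) were left out of everything that needs a gene or a sequence. A peak was proximal when it lay within 1 kb of a TSS and distal when it lay more than 2.5 kb from every TSS. A promoter was marked when a peak reached within 1 kb of any TSS of the gene. A distal peak was assigned to the gene with the nearest TSS, which need not be the gene it acts on.

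A peak counted as shared when at least 50% of its length, or of the overlapping peak's length, was covered. Random expectations came from 100 placements of the same intervals on the same chromosome, outside assembly gaps. Gene lists and motif words were fixed before the data were examined, as were the tests. Promoter marking of 16 gene lists was tested with a two-sided Fisher's exact test against all other protein-coding genes. The mean number of distal peaks per gene was tested with a two-sided permutation test against 10000 random lists matched on the tenth of the gene's territory, the span nearer to its TSSs than to any other. For 25 motif words, 500 bp windows centred on distal peaks were set against windows 5 kb away that touch no pooled peak, matched 1 to 1 on GC in steps of 2 percentage points, with a two-sided Fisher's exact test. Benjamini-Hochberg adjustment ran over the lists or over the words, with a threshold of 0.05. Genes, peaks and windows are not biological replicates, so these tests describe these libraries. Promoters were CpG-rich when the observed over expected CpG was at least 0.6 and GC at least 50% within 500 bp of the TSS. Domains were replicated peaks merged when at most 10 kb apart, ranked by covered base pairs. With 2 samples no exact test across samples can reach the threshold, so replicate spread is given as both values or as mean ± SD (n = 2). The pooled and replicated lists are the authors' lists and have no n.

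Genes were named by a rule fixed before the data were examined: the nearest gene, or the genes inside, for the 20 domains with the most covered base pairs; from each gene list the 3 members with the most base pairs covered within 50 kb of a TSS and up to 2 members without a marked promoter; the highest and lowest covered gene of each of the 4 Hox clusters; the nearest gene of the 10 peaks with the highest fold; and Shh, Fgf8, Fgf10, Grem1, Hand2, Gli3, Tbx4, Tbx5 and Pitx1. Any other gene is said to have been chosen after its values were seen. The text names the informative part of this set.

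The methods were tested on simulated data made from the real lists and genes. Of peaks copied between simulated lists 99.2% were found shared. Of random gene lists 5% passed 0.05 in the promoter test over 21911 genes, and 91% of lists of 20 genes with 95% marked promoters were found. In the distal test 4% of unchanged lists with long territories passed when matched and 50% when not, and 86% of lists with tripled counts were found. The homeodomain word had an odds ratio of 1.09 in unchanged windows (Fisher's exact test, p = 0.17) and 1.42 when put into 5% of the windows of 1 side.

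Alternatives tried were other overlap rules (1 bp, reciprocal 50%), only peaks with −log10 q of at least 2 or fold of at least 4, each replicate's list alone, the pooled list, fold as the measure of strength, a TSS window of 2.5 kb or the gene's 5' end only, CpG-rich promoters only, other matching of random lists, merging at 3 kb or 20 kb, windows of 200 bp at the authors' summit and flanks 20 kb away. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, with seed 20240.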

Results

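Active chromatin of the embryonic mouse limb was surveyed at embryonic day 10.5, when the limb buds are growing out and are being patterned. H3K27ac peak lists from 2 biological replicates, and the authors' pooled and replicated lists made from them, were examined to describe which promoters, distal regions and developmental genes carried the mark. Replicate 1 had 132279 peaks covering 65.9 Mb and replicate 2 had 137784 peaks covering 81.3 Mb. The authors' pooled list held 179182 peaks over 101 Mb and their replicated list 79850 peaks over 76.3 Mb, which is 2.88% of the sequenced genome. Median peak width was 283 bp in replicate 1, 326 bp in replicate 2 and 629 bp in the replicated list. All folds and p-values of single peaks are the authors' own, and the sequencing depth behind them is unknown.

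The first question was which part of each replicate's list recurred in the other. Of the peaks of replicate 1, 55.8% were shared with replicate 2, against 4.33 ± 0.0528% (SD over 100 random placements). Of the peaks of replicate 2, 46.9% were shared with replicate 1, against 4.03 ± 0.0532% at random. Shared peaks were wider and stronger: in replicate 1 their median width was 426 bp against 219 bp for peaks that were not shared, and their median fold 3.72 against 2.86. In replicate 2 the corresponding widths were 604 bp and 248 bp, and the folds 4.22 and 2.89. Recurrence rose with strength. When each list was split into 5 equal parts by −log10 p, in the weakest part 30.1% of replicate 1 peaks and 17.7% of replicate 2 peaks were shared, and in the strongest part 98.5% and 97.4%. A stricter rule, 50% of both peaks, lowered the shared part to 33.1% and 31.8%.

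**Figure D1:**
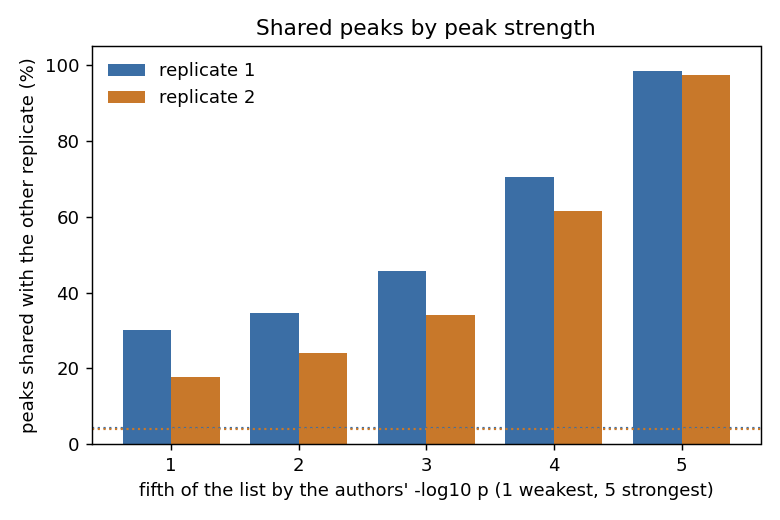
Percent of peaks shared with the other replicate (y axis) in 5 equal parts of each list ranked on the authors' −log10 p (x axis), for replicate 1 (blue) and replicate 2 (orange). Dotted lines give the mean of 100 random placements of each whole list, and no random share was computed for the single parts. The share rose from 30.1% to 98.5% in replicate 1 and from 17.7% to 97.4% in replicate 2.

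Over 51034 pairs of peaks that matched one to one, the folds of both replicates had a Pearson r of 0.896 on the log2 scale and a Spearman rho of 0.677, across peaks, which are not independent replicates. The median log2 ratio of replicate 2 over replicate 1 was 0.15 with an SD of 0.44 over peaks, and 96.8% of pairs lay within 2-fold. Folds come from separate libraries of unknown depth, so this ratio describes the lists and not the tissue. Every peak of the replicated list was a pooled peak with the same coordinates, fold and p. The 65271 pooled peaks that overlapped both replicate lists were all in the replicated list. A further 14579 replicated peaks (18.3%) did not overlap both lists by the 50% rule, of which 4109 overlapped only replicate 1, 10050 only replicate 2 and 420 neither. Their median fold was 3.01, against 4.07 for peaks that overlapped both lists and 2.53 for pooled peaks outside the replicated list.

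Promoters carried the strongest marks and distal regions the most peaks. Of replicated peaks, 23.0% lay within 1 kb of a TSS, against 5.62 ± 0.0764% (SD) in random placements, a ratio of 4.08, and 72.1% were distal. The proximal share was 18.3% in replicate 1 and 16.8% in replicate 2. Proximal peaks had a median width of 1261 bp and a median fold of 9.52, distal peaks 551 bp and 3.50. The ratio of median folds was 1.59 in replicate 1 and 1.94 in replicate 2, below the 2.72 of the replicated list, and proximal peaks had the higher median in both. Among the 5000 replicated peaks of highest −log10 p, 92.0% were proximal. Judged by the peak's centre, 43.7% of distal peaks lay in introns, 3.78% in exons and 52.5% outside protein-coding genes. In all, 22568 peaks had their centre more than 50 kb from any TSS. The proximal share was 40.1% when only peaks with a fold of at least 4 were kept.

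The 10 peaks of highest fold all reached a TSS. They included peaks at the cytoskeletal actin gene Actg1 (chromosome 11, 120347270 to 120352260, fold 59.5), Lmnb1, which encodes a nuclear lamina protein (fold 57.1), and the RNA-binding protein genes Ptbp2 (57.1), Hnrnpa3 (55.8) and Hnrnpk (55.5). Tnpo1, a nuclear import receptor gene, reached 55.8. The others lay at genes of DNA-binding proteins, Zfp532 (chromosome 18, 65575564 to 65585993, fold 58.5), Tead2 (58.4), Zfhx3 (56.0) and Hmga2 (55.4). At the Actg1 peak the fold was 45.0 in replicate 1 and 56.2 in replicate 2, and at Hmga2 43.9 and 41.5.

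Of 21911 protein-coding genes, 14272 (65.1%) had a promoter marked in the replicated list, with 14730 in replicate 1 and 14724 in replicate 2. CpG-rich promoters were marked in 96.2% of cases (9357 of 9725) and other promoters in 40.3% (4915 of 12186), an odds ratio of 37.6 by Fisher's exact test, with a p below the smallest value the software can represent. The odds ratio was 38.7 in replicate 1 and 37.5 in replicate 2.

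All 30 genes of the limb bud mesenchyme list had a marked promoter (Fisher's exact test, adjusted p = 2.5e-05), against 65.1% of other genes, and so did all 22 housekeeping genes (exact adjusted p = 0.00056). Limb signalling genes were marked in 26 of 28 cases (exact adjusted p = 0.0036), anterior Hox genes in 22 of 23 (exact adjusted p = 0.0038) and posterior Hox genes in 15 of 16 (exact adjusted p = 0.032). The limb signalling genes without a marked promoter in the replicated list were Shh and Wnt3. Shh was marked in replicate 1, Wnt3 in replicate 2, and both in the pooled list. Fewer promoters than elsewhere were marked among liver and gut endoderm genes, 5 of 21 (exact adjusted p = 0.00056), germ line and pluripotency genes, 5 of 16 (exact adjusted p = 0.016), and olfactory and taste receptors, 5 of 1169, for which the exact p was below the smallest value the software can represent. In replicate 1 alone, 10 of 21 endoderm promoters and 7 of 16 germ line promoters were marked, and neither list passed there (exact adjusted p = 0.10 for both). Posterior Hox genes did not pass in replicate 1 either (exact adjusted p = 0.062), in the pooled list (exact adjusted p = 0.12) or with a TSS window of 2.5 kb (exact adjusted p = 0.054). The endoderm and germ line lists did not pass in the pooled list (exact adjusted p = 0.38 and 0.40).

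**Figure D2:**
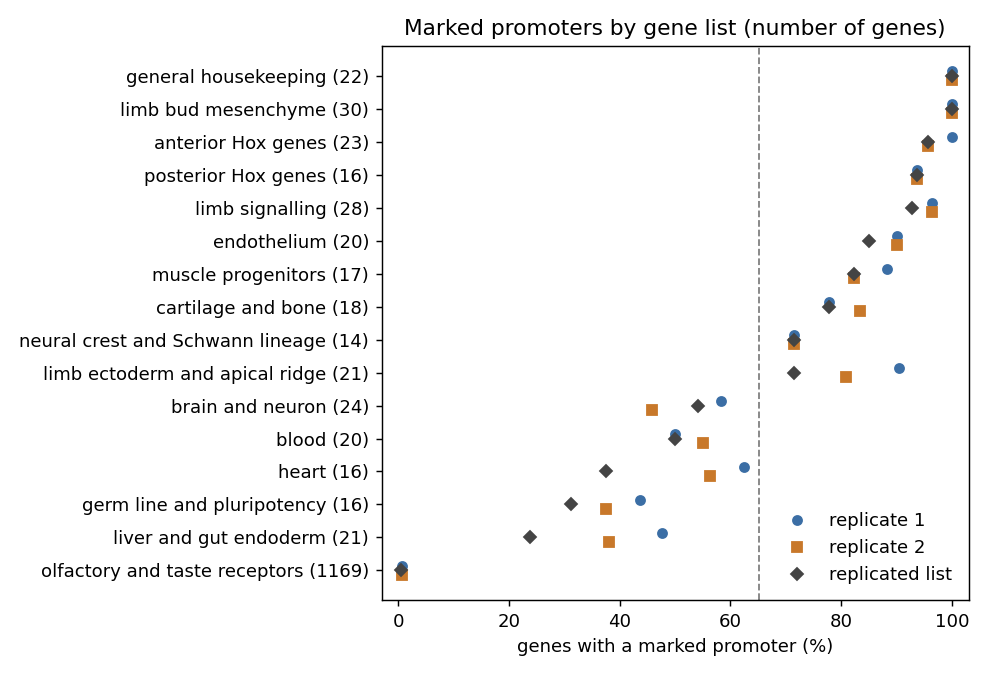
Percent of each fixed gene list with a marked promoter (x axis), for replicate 1 (blue circles), replicate 2 (orange squares) and the authors' replicated list (dark diamonds); the number of genes is in parentheses and the dashed line is the 65.1% of all protein-coding genes in the replicated list. Limb mesenchyme and housekeeping genes lay at 100% and olfactory and taste receptors at 0.428%.

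The other 8 lists did not pass. Marked promoters numbered 14 of 18 for cartilage and bone, 15 of 21 for limb ectoderm and apical ridge, 14 of 17 for muscle progenitors, 17 of 20 for endothelium, 10 of 20 for blood, 10 of 14 for neural crest and Schwann lineage, 13 of 24 for brain and neuron and 6 of 16 for heart. Limb ectoderm had 19 of 21 in replicate 1 (odds ratio 3.81) and 17 of 21 in replicate 2 (1.90), and passed in neither. Endothelium passed in replicate 2 (exact adjusted p = 0.050, just below the threshold of 0.05) and in the pooled list (exact adjusted p = 0.034), and brain and neuron, marked less often, passed in replicate 2 (exact adjusted p = 0.050, again just below 0.05). With a fold of at least 4 brain and neuron (odds ratio 0.147) and heart (0.174) passed, as they did at the gene's 5' end only (0.325 and 0.301), and heart passed with only peaks that overlap both replicate lists (0.202). Heart did not pass in replicate 1 (10 of 16, odds ratio 0.787), replicate 2 (9 of 16, 0.618) or the pooled list (11 of 16, 0.913). Brain and neuron did not pass in replicate 1 (0.673) or the pooled list (1.02). Promoters without a replicated peak were those of the late cartilage gene Col10a1, the skin keratin gene Krt14, the myogenic factors Pax7 and Myod1, the erythroid regulator Gata1, the forebrain factor Foxg1, the heart factors Nkx2-5 and Gata4, the liver genes Alb and Afp and the pluripotency factor Nanog. Of these, Krt14 was marked in replicate 2, Myod1 in replicate 1, and both of them, Nkx2-5 and Gata4 in the pooled list. The others were unmarked in every list. Alb and Afp had no peak within 50 kb in either replicate. When only CpG-rich promoters were compared, the lists of limb mesenchyme (odds ratio 1.70), limb signalling (0.512), posterior Hox (0.828), anterior Hox (1.14), housekeeping (1.54) and liver and gut endoderm (0.0917) no longer passed. The olfactory and taste receptor list had no CpG-rich promoter, so it was not tested there. Its odds ratio of 0.0394 came only from a small constant added to every count. The 3 lists that passed there, brain and neuron, heart, and germ line and pluripotency, were all marked less often than other genes. Of all CpG-rich promoters 96.2% were marked, so short lists could not pass there by being marked more often. The odds ratios, with a small constant added to every count, can also fall below 1 for short lists marked in full. The calls lost there therefore do not show that CpG content accounts for the limb, Hox or housekeeping results. Nor do they show it for endoderm genes, few of which had a CpG-rich promoter, or for the receptor genes, which were not tested there.

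Distal peaks gathered around genes of limb mesenchyme. Limb mesenchyme genes had a mean of 21.0 distal replicated peaks each, against 7.25 for random lists of like territory (permutation test, adjusted p = 0.0016, from the smallest p that 10000 random lists can give). The means per replicate were 36.2 and 36.2. Cartilage and bone genes had 19.1 against 4.72 (permutation test, adjusted p = 0.0043) and limb signalling genes 15.9 against 6.61 (permutation test, adjusted p = 0.027), with replicate means of 32.6 and 37.8 for cartilage and bone and 26.5 and 27.2 for limb signalling. The mean for cartilage and bone rested on few genes, since its median was 2.5. Olfactory and taste receptors had 0.0915 against 0.608 (permutation test, adjusted p = 0.0016), with replicate means of 0.120 and 0.152. Anterior Hox genes had 1.48 against 0.409 and brain and neuron genes 1.79 against 5.13, and neither passed (permutation test, adjusted p = 0.065 and 0.13). Replicate means were 2.74 and 2.65 for anterior Hox genes and 4.96 and 4.46 for brain and neuron. Anterior Hox genes passed in replicate 1, in replicate 2 and in the pooled list (permutation test, adjusted p = 0.021, 0.031 and 0.044). Limb signalling missed the threshold when all distal peaks within 50 kb were counted whatever the nearest gene (permutation test, adjusted p = 0.068), and so did cartilage and bone (permutation test, adjusted p = 0.068). Limb signalling also missed it when random lists were matched on a marked promoter as well as territory, with a ratio to random lists of 1.91 (permutation test, adjusted p = 0.080).

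Among limb mesenchyme genes the most bases were covered within 50 kb of Prrx2, 71270 bp in the replicated list and 63819 ± 8101 bp (SD, n = 2) in the replicates, but 4 other genes have a TSS in that window. Tbx4, a T-box factor of the hindlimb bud, followed with 56399 bp (50089 ± 10492 bp, SD, n = 2) and 49 distal peaks, and Snai1 with 43965 bp (40287 ± 3553 bp, SD, n = 2). Tbx5, the T-box factor of the forelimb bud, had 38146 bp (36983 ± 2237 bp, SD, n = 2) and 17 distal peaks. Hand2, a factor of the posterior limb bud, had 30081 bp (27916 ± 5136 bp, SD, n = 2), and Pitx1, a hindlimb factor, 20441 bp (19132 ± 491 bp, SD, n = 2). Bmp7 had 66 distal peaks and Fgfr2 52, although the annotated span of Fgfr2 in this annotation is long. From 50 kb before the first to 50 kb after the last TSS of Fgfr2, 30 other genes have a TSS. Fgf10, the mesenchymal growth factor of limb outgrowth, had 7005 bp and 17 distal peaks, Gli3 7360 bp and 22, Fgf8, made by the apical ridge, 7182 bp and 4, and Grem1 4333 bp and 0. Distal peaks in replicates 1 and 2 numbered 60 and 74 at Tbx4, 24 and 28 at Tbx5, 106 and 96 at Bmp7, 85 and 92 at Fgfr2, 27 and 20 at Fgf10, 47 and 47 at Gli3, 6 and 8 at Fgf8 and 2 and 0 at Grem1.

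Shh, the signal of the posterior margin of the limb bud, whose known limb enhancer lies far outside a 50 kb window, had no replicated peak within 50 kb of its TSS and no marked promoter in the replicated list, and 1 distal replicated peak was nearest to it (5 and 3 in the replicates). Replicate 1 covered 1603 bp within 50 kb of Shh and marked its promoter, and replicate 2 covered 0 bp. The cartilage genes Sox5 and Sox6 had 80 and 57 distal replicated peaks (144 and 152 in the replicates for Sox5, 92 and 111 for Sox6). Col2a1 had 4 (8 and 9), and Ihh, a signal of later cartilage, had 2 (5 and 3) with no marked promoter in the replicated list but 1 in replicate 2. In the ectoderm list the most covered genes were Sp6 (18554 bp), Tfap2a (16559 bp) and Krt8 (14219 bp), and Trp63, the regulator of surface ectoderm, had no marked promoter in the replicated list but had 1 in replicate 1. Endothelial genes Eng (48605 bp) and Fli1 (31971 bp) and the neural crest receptor gene Ngfr (38640 bp) were also widely covered, the Eng window holding TSSs of 5 other genes and those of Fli1 and Ngfr of 0.

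The Hox clusters were covered in blocks. Over the Hoxa cluster (chromosome 6, 52155590 to 52261880) replicated peaks covered 79.0% of the bases, and the replicates 76.1 ± 0.387% (SD, n = 2). The Hoxd cluster (chromosome 2, 74667310 to 74765142) was covered to 62.6% (60.3 ± 5.03%, SD, n = 2), the Hoxc cluster (chromosome 15, 102920103 to 103036852) to 60.6% (55.2 ± 2.16%) and the Hoxb cluster (chromosome 11, 96193316 to 96368256) to 35.9% (33.4 ± 4.53%). Hoxb13 lies 74009 bp from the next gene of its cluster, and from Hoxb9 on, a span chosen after its values were seen, Hoxb was covered to 61.1% (56.2 ± 7.41%, SD, n = 2). All 11 Hoxa, 9 Hoxc and 9 Hoxd promoters were marked, and 8 of 10 Hoxb promoters, those of Hoxb1 and Hoxb13 being unmarked. The Hoxb1 promoter was marked in replicate 1, which covered 12.6% of the gene and 1 kb upstream, and in the pooled list. That of Hoxb13 was marked in no list. The longest replicated peak of the genome spanned 48190 bp of the Hoxa cluster (chromosome 6, 52202411 to 52250600) and covered Hoxa6, Hoxa7, Hoxa9, Hoxa10 and Hoxa11 in full. A peak of 23751 bp lay over the Hoxd cluster and covered Hoxd9, Hoxd10 and Hoxd11 in full, and 1 of 22576 bp covered Hoxc11 in full. The longest peaks there were shorter in the replicates, 35191 and 36290 bp in Hoxa and 15918 and 23349 bp in Hoxd. In Hoxc replicate 2 had a peak of 22318 bp, but the longest of replicate 1 was 5174 bp. Replicate 1 covered Hoxc11 to 92.8%, Hoxd11 to 96.6% and Hoxa7 to 98.1%, and replicate 2 covered Hoxa6 to 98.5%.

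Within the clusters the least covered genes, counted over the gene and 1 kb upstream, were Hoxa1 (50.5% of bases), Hoxb1 and Hoxb13 (0%), Hoxc13 (13.2%) and Hoxd1 (35.5%). The highest coverage was 100% in the Hoxa, Hoxc and Hoxd clusters, reached at Hoxc11 alone in Hoxc, and 95.1% at Hoxb2 in the Hoxb cluster. Hoxa13, used in the distal limb bud, was covered to 55.7% in replicate 1 and 92.6% in replicate 2, and Hoxd13 to 85.5% and 74.8%. Hoxb8 was covered to 68.4% in replicate 1 and 53.0% in replicate 2, and Hoxc8 to 49.2% and 21.6%. Hoxa13, Hoxd13, Hoxb8 and Hoxc8 were chosen after their values were seen. Long annotated transcripts of Hoxa3, Hoxc5 and Hoxd3 run across neighbouring genes, so coverage of those genes was not read alone.

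**Figure D3:**
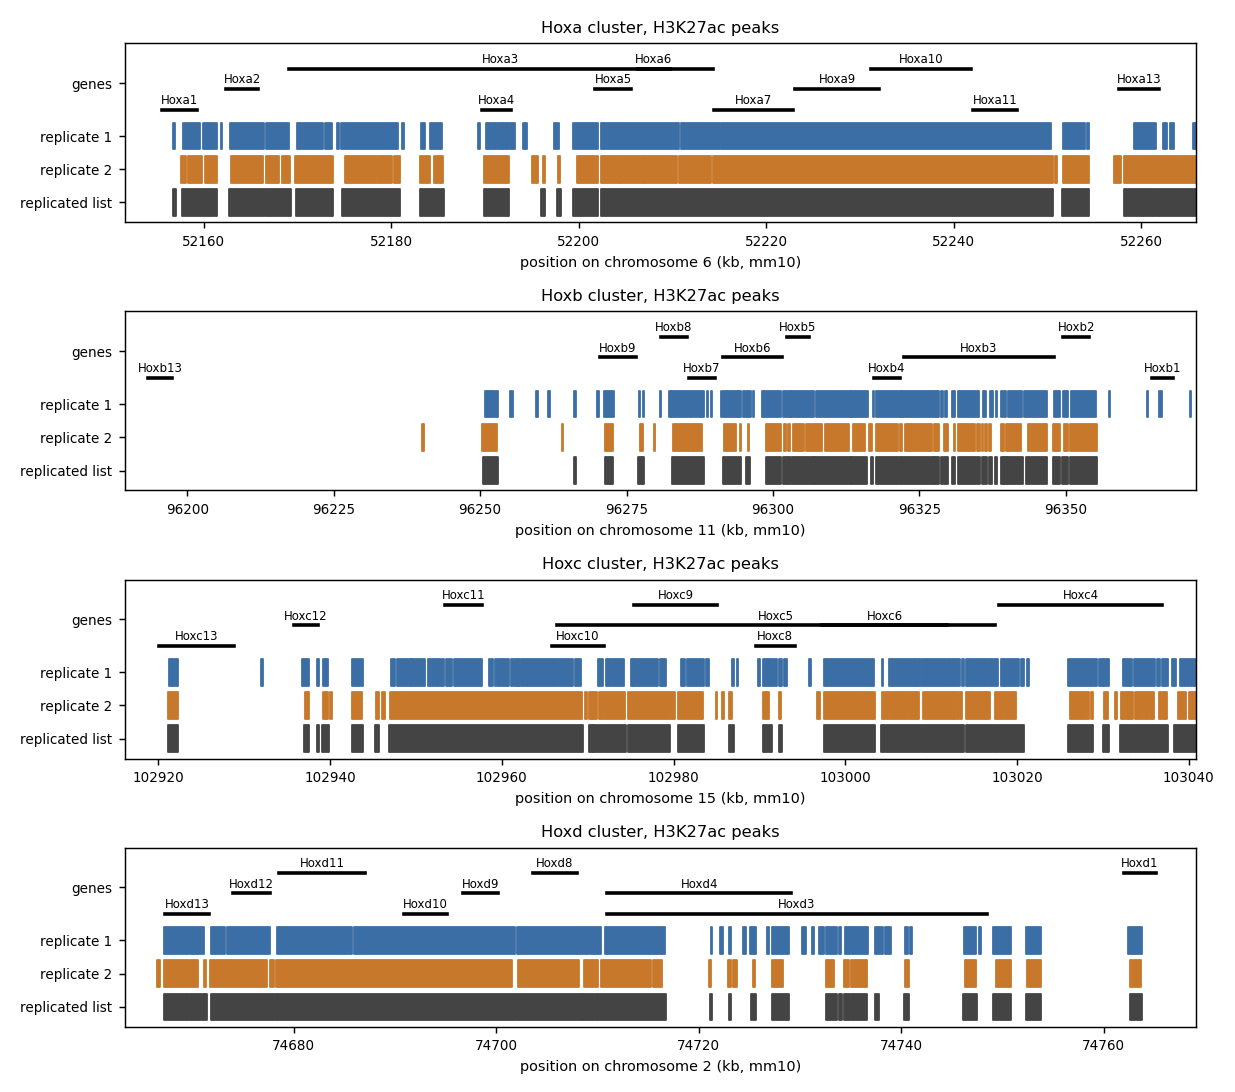
Maps of the Hox clusters A to D on mm10 (x axis, position in kb), with peaks of replicate 1 (blue), replicate 2 (orange) and the authors' replicated list (dark) as blocks, and genes with 1 kb upstream as black lines above. A block of 48190 bp covers the Hoxa cluster from Hoxa6 to Hoxa11, and Hoxb13 has no peak.

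Merging replicated peaks at most 10 kb apart gave 28563 domains with a median of 1368 covered bp, of which 395 held more than 20 kb. The most extended domain lay on chromosome 2 (166134163 to 166575133) over Sulf2, which encodes a sulfatase acting on heparan sulfate, and Prex1. It held 197 peaks and 243006 covered bp, with 208132 ± 42553 bp (SD, n = 2) in the replicates. Next were a domain over Gse1 (chromosome 8, 185172 bp), 1 over the imprinted gene Mest with Cep41 and the Cpa genes (chromosome 6, 177684 bp), 1 over Dnm3 and Pigc (chromosome 1, 166927 bp) and 1 over Prdm16 (chromosome 4, 146953 bp). Further domains lay over Cstad and Ntmt1, over Tnnt3, Lsp1 and Mrpl23 (chromosome 7, 142427877 to 142614468, 142424 bp), over Dysf, over the Hoxa genes (95564 bp), and over Dusp7, Bahcc1, Spsb1, Vegfa, Mecom, Igfbp4, Peg3 with Usp29, and Ssbp3 with Acot11. Domains without a protein-coding gene inside lay nearest Foxl1 (centre 157143 bp from its TSS), Haao (103890 bp) and Zfp36l1 (153048 bp). Replicate 2 covered more bases than replicate 1 in all 20 domains. Of the 20 domains, 14 were among the 20 of replicate 1 and 16 among those of replicate 2. The domains depended on the merging distance, and 13 recurred at 3 kb and 12 at 20 kb.

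**Figure D4:**
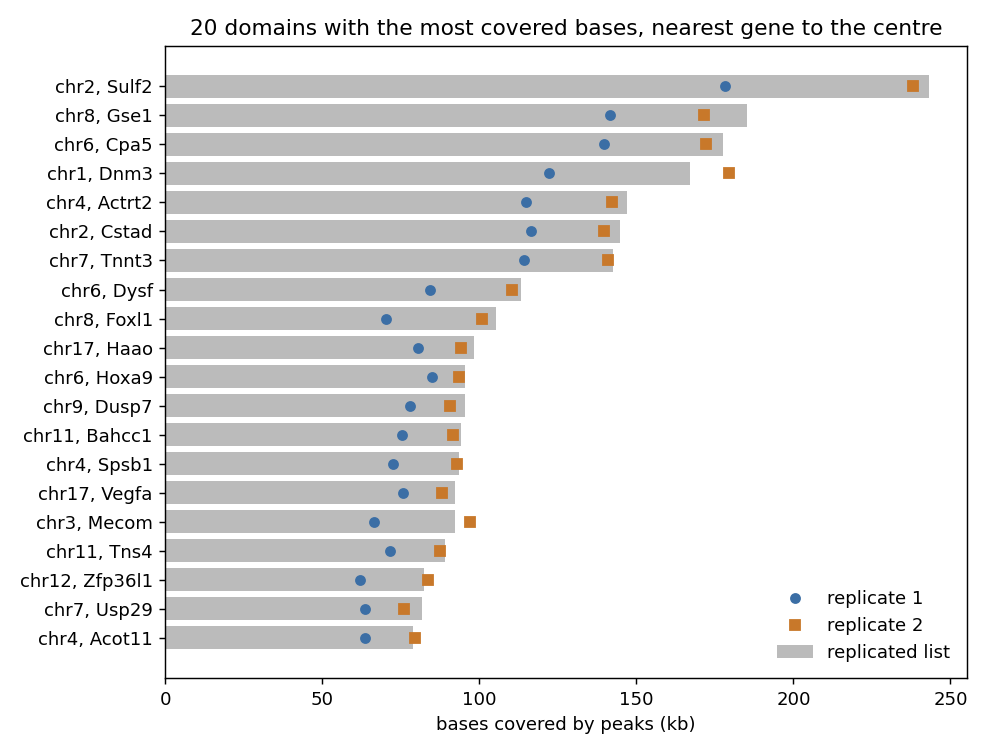
Bases covered by peaks (x axis, kb) in the 20 domains with the most covered bases, named by chromosome and the gene nearest the domain's centre, for the authors' replicated list (grey bars), replicate 1 (blue circles) and replicate 2 (orange squares). Covered bases ran from 243006 bp at Sulf2 to 78931 bp at Acot11, and replicate 2 lay above replicate 1 in each.

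Words of homeodomain and TEAD factors and the E-box CAGCTG were more frequent in distal peaks than in GC-matched flanks. Of 25 words, 12 were more frequent and 5 less frequent past the threshold, over 36487 windows on each side. GC matching kept these from 57588 distal peak windows, and mean GC of the peak windows went from 50.8% to 48.2%. The results describe the matched windows, and GC-rich distal peaks were left out more often. The homeodomain core word TAATTA was in 11.3% of peak windows and 8.58% of flank windows (odds ratio 1.36, Fisher's exact test, adjusted p = 2.3e-33). The composite PBX-HOX word TGATTDAT had an odds ratio of 1.21 (exact adjusted p = 1.7e-07), the posterior HOX word 1.08 (exact adjusted p = 0.011) and the TCF/LEF word of Wnt signalling 1.14 (exact adjusted p = 0.00082). The E-box CAGCTG, bound by factors of the MYOD type and others, was in 30.8% against 25.3% (odds ratio 1.31, exact adjusted p = 6.1e-59). TEAD (1.28), RUNX (1.19), SOX (1.09), MEF2 (1.47), ETS (1.43) and SP/KLF (1.32) words were more frequent too. The highest odds ratio, 1.71, was that of the insulator factor CTCF, whose word was in 0.630% of peak windows and 0.370% of flank windows (exact adjusted p = 1.8e-06). In windows of 200 bp at the authors' summit the CTCF odds ratio was 0.520 (exact adjusted p = 0.0097), below 1. There posterior HOX (0.997) and SP/KLF (0.870) fell below 1 without passing, and PBX-HOX (1.07), TCF/LEF (1.15) and ETS (1.27) did not pass. Posterior HOX did not pass with −log10 q of at least 2 (1.03). With a fold of at least 4, TCF/LEF (1.14), SOX (1.06), ETS (1.37) and RUNX (1.13) did not pass, and SOX did not pass in replicate 2 alone (1.02) or with repeat content matched as well as GC (1.06). When words inside repeats were left out of the windows matched in that way, ETS (1.24, exact adjusted p = 0.051) and SOX (1.07, exact adjusted p = 0.056) did not pass.

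Words of NFY (odds ratio 0.743), PITX/OTX (0.790), T-box factors (0.834), nuclear receptors (0.916) and MEIS/TALE factors (0.946) were less frequent in distal peaks. The MEIS/TALE word did not pass in the pooled list (0.983), in replicate 1 alone (0.992) or in windows of 200 bp (0.968), and the T-box word did not pass with a fold of at least 4 (0.847). The PITX/OTX odds ratio was 0.919 when the windows were also matched on repeat share, and 1.04 when words inside repeat-masked bases were left out of those matched windows. The GLI word of Hedgehog signalling had an odds ratio of 1.09 and the E-box CATCTG of TWIST and HAND 1.03, and neither passed (exact adjusted p = 0.48 and 0.098). GATA, AP-1, SRF, EBF, NRF1 and REST words did not pass either. GLI passed in replicate 2 alone, in the pooled list and with −log10 q of at least 2, and the E-box of TWIST and HAND in each replicate alone, in the pooled list, with flanks 20 kb away and with only peaks that overlap both replicate lists, at an odds ratio of at most 1.05. Each of the other 6 passed in at least 1 alternative.

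**Figure D5:**
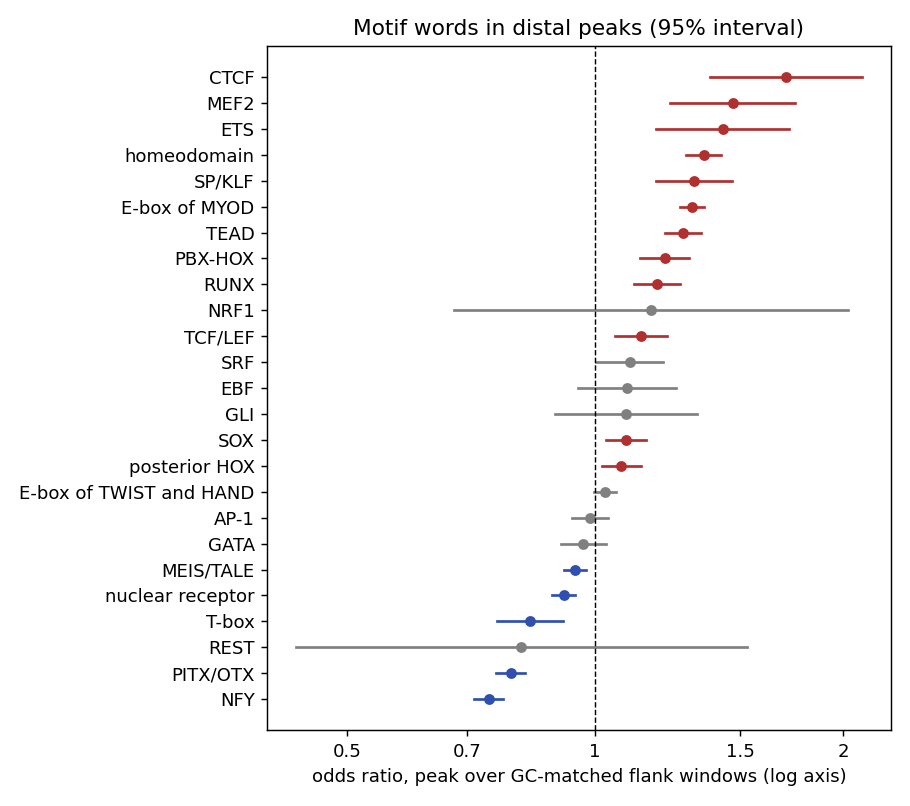
Odds ratio (x axis, log scale) of a window holding each motif word, distal peaks of the replicated list over GC-matched flanks, with 95% intervals; red is more frequent, blue less frequent and grey not past the adjusted threshold. CTCF lay highest at 1.71 and NFY lowest at 0.743.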

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

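The replicated list held 9 peaks on unplaced contigs, sequence that is not assigned to a chromosome. They were left out of every result that needs a gene, a domain or a sequence. They stayed in the list totals and in the overlaps between lists. They were picked out because their number is above 3, the limit that a count of 0 allows. They lay on 5 contigs and had folds from 1.70 to 35.9, with a median of 3.86, in the authors' values. Replicate 1 had 9 such peaks and replicate 2 had 8. No explanation was tested for them.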

How the results depend on the processing

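Alternatives chosen after seeing the data were GC and repeat content matched together, only those replicated peaks that overlap both replicate lists, territory and marked promoter matched together, and the Hoxb cluster from Hoxb9 on, which was covered to 61.1%. The cause of the changes below was not tested. Using each replicate's list alone gave a promoter share of 16.8% to 18.3%, a width ratio of proximal over distal peaks of 2.43 to 2.72, a fold ratio of 1.59 to 1.94, 5 to 10 gene lists past the promoter threshold, and coverage of 75.8% to 76.3% for Hoxa, 30.2% to 36.6% for Hoxb, 53.6% to 56.7% for Hoxc and 56.7% to 63.8% for Hoxd. With the pooled list the promoter share was 14.6%, the width ratio 2.60, the fold ratio 1.66, coverage 81.7% for Hoxa and 64.8% for Hoxc, and 12 of the 20 domains with the most covered bases recurred. With a fold of at least 4 the promoter share was 40.1%, the width ratio 1.52, coverage 77.9% for Hoxa, 30.5% for Hoxb and 53.8% for Hoxc, 13 of the 20 domains recurred, 81.0% and 65.3% of the peaks of replicates 1 and 2 were shared, and rho of the folds was 0.878. With −log10 q of at least 2, 64.7% of replicate 1 peaks were shared and rho was 0.741; reciprocal 50% overlap gave 33.1% and 31.8% shared and rho 0.822; 1 bp overlap gave 37.2% of pooled peaks overlapping both replicate lists, against 36.4%. Only peaks that overlap both replicate lists gave a promoter share of 26.1% and 78.4% of Hoxa. A TSS window of 2.5 kb gave a promoter share of 27.9% and the gene's 5' end only 16.7%. Merging at 3 kb kept 13 of the 20 domains and at 20 kb kept 12. The values below are odds ratios for promoters and motif words and ratios to random lists for distal peaks, and a ratio on the other side of 1 from the main value counts as reversed. Among CpG-rich promoters only, 3 gene lists passed. The promoter odds ratio reversed for limb signalling (0.512), posterior Hox genes (0.828), cartilage and bone (0.118), limb ectoderm (0.197), muscle progenitors (0.197), endothelium (0.433) and neural crest (0.433), none past the threshold. A small constant was added to every count of these odds ratios, and 96.2% of all CpG-rich promoters were marked. Short lists marked in full can therefore fall below 1, so these reversals do not show fewer marked promoters. The promoter odds ratio lost the threshold for limb bud mesenchyme (1.70), anterior Hox genes (1.14), liver and gut endoderm (0.0917) and housekeeping (1.54), and gained it for brain and neuron (0.0447) and heart (0.0392). Few endoderm and heart genes had a CpG-rich promoter, so those values rest on a small part of each list. Olfactory and taste receptors (0.0394) had no CpG-rich promoter and were not tested there, the value coming from the added constant alone. With a fold of at least 4, cartilage and bone (0.832), limb ectoderm (0.737), muscle progenitors (0.752), endothelium (0.815) and neural crest (0.515) reversed without a call, as did the GATA word (1.01), and the NRF1 word came to exactly 1.00. Brain and neuron (0.147), heart (0.174), AP-1 (0.890) and SRF (1.31) gained the threshold, and T-box (0.847), TCF/LEF (1.14), SOX (1.06), ETS (1.37) and RUNX (1.13) lost it. With −log10 q of at least 2, posterior HOX (1.03) lost it and GLI (1.27) gained it. Each replicate's list alone gave promoter odds ratios of 5.04 to 5.05 for posterior Hox genes, 3.61 to 3.62 for endothelium, 0.415 to 0.673 for brain and neuron, 0.307 to 0.445 for liver and gut endoderm and 0.302 to 0.385 for germ line and pluripotency, and a distal ratio of 3.48 to 3.55 for anterior Hox genes. Endothelium and brain and neuron passed in replicate 2, the other 3 promoter lists did not pass in replicate 1, and the distal call passed in both. For words the ranges were 0.968 to 0.992 (MEIS/TALE), 1.02 to 1.05 (TWIST and HAND), 1.14 to 1.19 (GLI), 1.02 to 1.05 (SOX), 1.05 to 1.16 (EBF), 1.07 to 1.09 (SRF) and 0.5998 to 0.759 (REST), each passing or failing unlike the main value in at least 1 replicate. With the pooled list, promoters of posterior Hox genes (4.52), liver and gut endoderm (0.574) and germ line and pluripotency (0.553) and the MEIS/TALE word (0.983) lost the threshold. Promoters of endothelium (5.68), distal peaks of anterior Hox genes (2.93) and the words of TWIST and HAND (1.03), GLI (1.27), NRF1 (1.57) and REST (0.660) gained it, and brain and neuron promoters (1.02) reversed without a call. With a TSS window of 2.5 kb posterior Hox genes (5.18) lost the threshold and heart (1.05) reversed without a call, and at the gene's 5' end only brain and neuron (0.325) and heart (0.301) gained it. With only peaks that overlap both replicate lists heart promoters (0.202), TWIST and HAND (1.05) and EBF (1.23) gained it, and distal peaks of neural crest (1.00) reversed without a call. Counting distal peaks within 50 kb whatever the nearest gene, limb signalling (2.01) and cartilage and bone (2.41) lost the threshold, posterior (2.66) and anterior (3.40) Hox genes gained it and neural crest (1.31) reversed without a call. With territory and marked promoter matched, limb signalling (1.91) lost it. With no territory matching, posterior (0.352) and anterior (0.566) Hox genes, neural crest (1.48) and housekeeping (0.312) reversed without a call. In 200 bp windows at the authors' summit 6 words were more frequent. CTCF (0.520) reversed past the threshold, posterior HOX (0.997) and SP/KLF (0.870) reversed and lost it, GLI (0.989), GATA (1.03) and NRF1 (0.5999) reversed without a call, and PBX-HOX (1.07), MEIS/TALE (0.968), TCF/LEF (1.15) and ETS (1.27) lost it. With flanks 20 kb away TWIST and HAND (1.03), GATA (0.933) and REST (0.370) gained the threshold and AP-1 (1.03) reversed without a call. With GC and repeat content matched SOX (1.06) lost it, GATA (0.921) gained it and TWIST and HAND (0.997) reversed without a call. All other tests of these alternatives kept direction and side of the threshold, 108 of promoter lists, 130 of distal lists and 182 of motif words. The search outside repeat-masked bases, in windows matched on GC and repeat content, is not in these counts. There PITX/OTX (1.04) reversed and lost the threshold, ETS (1.24) and SOX (1.07) lost it, and GATA (0.926) gained it. Bases covered near the named genes stayed within the spread of the replicates in 70 comparisons, rose in 14 and fell in 30. The direction of the CpG result held in every alternative run. Depth is unknown, so whether weak peaks found in 1 replicate were missed in the other for lack of reads was not tested. No paired analysis was possible because there is 1 group.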

Other observations

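Genes with the most distal replicated peaks were chosen after their values were seen. Zmiz1 had 203, Zfhx3 175, Gse1 155, Prex1 139 and Zfp36l1 132, and the chondrogenic factor Sox9 had 127 spread over a territory of 1249796 bp. Relative to territory, Gse1 had 41.2 peaks per 100 kb and Sox9 10.2. In replicate 2 the counts at Sox9 and Zmiz1 were 261 and 330, and in replicate 1 they were 192 and 313. In all, 736 replicated peaks lay more than 500 kb from any TSS of a protein-coding gene.

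Of the tests below, those of the forelimb share, of the repeat share of the flanks, of the PITX/OTX word and of gene number on the X chromosome were chosen after the result was seen. No biological explanation was tested by design, since there is 1 group.

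Relative to replicated peaks of like strength, the 78 peaks nearest anterior Hox genes were lower in replicate 2, with a median log2 ratio of −0.43 (95% bootstrap interval over genes −0.47 to −0.13). Ratios by gene list were not among the results planned in advance. The interval treats neighbouring genes of a cluster as independent and does not measure the spread between embryo pools. By cluster the medians were −0.27 (−0.52 to −0.09) for Hoxa, −0.46 (−0.62 to 0.03) for Hoxb, −0.13 (−0.51 to 0.18) for Hoxc and −0.46 (−0.52 to −0.28) for Hoxd, the last 2 with intervals over peaks. Peaks of limb ectoderm and apical ridge genes were lower in replicate 2 too, at −0.17 (−0.24 to −0.09), and no explanation was tested for them. Centring on GC as well left anterior Hox peaks at −0.41 (−0.48 to −0.11), which argues against GC content as the whole cause. Trunk tissue in replicate 1 would lower somite and neural tube markers in replicate 2 as well, but the 109 peaks of 28 such genes, 8 of them also in other lists, with a median fold of 4.15, had a median of 0.11 (0.05 to 0.19). Only peaks with a fold in both replicates entered, so marker peaks absent from replicate 2 could not count. That value thus speaks only for shared peaks of these markers, and other trunk tissue was not tested. A smaller share of forelimbs in replicate 2 would lower the forelimb gene Tbx5 and raise the hindlimb genes Tbx4 and Pitx1. The 14 Tbx5 peaks had a median of −0.11 (interval over peaks −0.20 to 0.03), and anterior Hox peaks minus Tbx5 peaks gave −0.32 (−0.48 to −0.01), an interval that only just excluded 0. The 42 Tbx4 peaks had a median of 0.15 (0.02 to 0.29) and the 18 Pitx1 peaks 0.15 (−0.18 to 0.33), so a smaller forelimb share stays open. A difference between the embryo pools, such as slightly different stages or dissection borders, may underlie the shift too and was not tested.

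Words less frequent in distal peaks than in flanks were those of NFY, PITX/OTX, T-box, nuclear receptor and MEIS/TALE factors. The flanks held more repeat-masked bases, 25.3% against 14.9%, yet all 5 words stayed less frequent past the threshold when repeat share was matched. When only bases outside repeats were searched in those matched windows, 4 of the 5 stayed less frequent (odds ratios 0.775 for NFY, 0.785 for T-box, 0.856 for MEIS/TALE and 0.886 for nuclear receptor), so repeat families do not account for those. The PITX/OTX word moved from 0.790 to 0.919 (95% interval 0.881 to 0.957) with repeat share matched, and to 1.04 (0.989 to 1.09) when words inside repeats were left out as well. Repeat sequence in the flanks, by its share and by the copies of that word in it, is thus a candidate explanation for this word alone. What lowers the other words stays open.

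The X chromosome had 6.38 replicated peaks per Mb, against 24.8 to 52.1 on the autosomes. Fewer genes do not account for it, since X had 1.10 peaks per gene (exact Poisson 95% interval 1.03 to 1.17) and the lowest autosome 2.42, nor does repeat sequence, since X had 12.0 peaks per Mb outside repeats and the lowest autosome 38.6. Of all CpG-rich promoters, 89.4% were marked on X against 96.4% on autosomes (Fisher's exact test, p = 4.7e-06). Folds were lower on X: CpG-rich promoters that were marked had a median of 11.7 against 18.6 on autosomes. With the fold minimum for autosomal distal peaks raised from 4 by that ratio of 1.59, X had 1.63 distal peaks per Mb (1.44 to 1.84) and the autosomes 1.72 to 3.61, against 1.63 and 6.25 to 11.9 with a minimum of 4 on both. A lower fold over the X chromosome, as a single active copy per cell in embryos of mixed sex might give, may therefore account for most of the gap and cannot be told apart from a true lack of distal peaks by these counts.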
